A study of Mus musculus with 23 samples.

How the data were processed

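Crosslinking and immunoprecipitation followed by sequencing (CLIP-seq) was analysed in 10 libraries from v6.5 mouse embryonic stem cells. Per the labels, the cells were grown on feeder fibroblasts and pre-plated to remove these before ultraviolet irradiation at 254 nm with 400 mJ/cm2. The libraries were made with a rabbit antibody against Upf1 or with control IgG, from untreated cells (A1, A2 and I for each antibody) or from cells treated with cycloheximide at 100 µg/ml for 2 hours (A1 and A2 for each antibody). The 10 mRNA-seq and 3 ribosome footprinting samples of the series were not analysed here. The labels do not say whether libraries of 1 group came from separate cultures, so p-values measure only the spread between these libraries.

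The deposited files list alignments, 1 per line, on mouse build mm9 and on a contig named chrRibo, whose sequence the labels do not describe. The submitters' processing notes name TopHat 1.4.0, Cufflinks 1.3.0 and Bowtie 0.12.6 without saying which of these made the alignments. In the deposited files the score column held the value 255 in every line, and carried no measurement. The other measured column of the deposited files is a name that joins a serial number, a number of copies and 2 letters. Per the labels, 2 random nucleotides in the 5′ adapter served to filter PCR copies. A position with the same letters occupied at most 2 lines in each Upf1 library and up to 1280 lines in IgG untreated A1, so the files of the antibodies had not been filtered alike. Each distinct alignment (chromosome, start, end and strand) was therefore counted once per library. The longest unspliced reads were 34 nt in Upf1 untreated A1, Upf1 untreated I and IgG untreated I, and 38 nt in the other libraries. All libraries with 34 nt reads were untreated.

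An alignment that spanned more than 60 nt was taken as spliced. Unspliced alignments of all 10 libraries were merged on the same strand where they lay at most 50 nt apart, which gave 203521 regions. A region was tested if it held at least 10 alignments over all libraries and was present in at least 3. These 2357 regions held 17.1% of the unspliced alignments. Coordinates are 1-based positions on mm9. No annotation of that build was at hand, so no region was assigned to a gene, and the planned tests of genes, of untranslated and coding sequence and of gene lists were not run.

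The values are tallies of lines and not a count table, so limma-voom (limma 3.58.1 in R 4.3.3) was used in place of a negative binomial tool. Scaling was by the trimmed mean of M values (TMM), with trims of 30% and 5%. Upf1 was compared with IgG in a model with treatment as a covariate. Cycloheximide was compared with untreated in a model of the 4 groups, which pools the spread over all groups. Adjusted p-values are Benjamini-Hochberg values over the tested regions, with a threshold of 0.05. The second tool was limma on log2 values scaled to library size, with an offset of 0.5 and a trended prior. The method was tested on simulated data with a dispersion of 0.3 in which 50 regions changed at each of 2-, 4-, 8- and 16-fold. For cycloheximide against untreated in Upf1 it recovered 0, 2, 3 and 15 of these, with 3 false calls, and at 16-fold all 15 were increases. For Upf1 against IgG it recovered 1, 11, 31 and 33, with 9 false calls, and recovered fewer decreases than increases.

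Regions were named by a rule set before the data were examined. It took the 10 regions with the lowest p in each direction among those past the threshold that moved the same way in both matched pairs of libraries. Where none passed, it took the 5 with the lowest p in each direction, and in addition the 5 regions with the most alignments. Where a group held no alignment in a region, the fold is a lower bound against 3 counts over that group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval.

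The composition of each library was described by 7 shares, each with a Wilson 95% interval. Groups were compared with exact two-sided permutation tests and Benjamini-Hochberg adjustment over the 7 shares. For cycloheximide against untreated in all 10 libraries, the labels were permuted within each antibody. This test, the spliced share, the chrRibo share, the 30 nt limit of a short alignment and the 3′ side share were chosen after the data had been seen. For the 3′ side share, the spans of spliced alignments up to 20000 nt long were merged, leaving out the mitochondrial chromosome and chrRibo. It is the share of unspliced alignments outside these spans and within 2000 nt on their 3′ side, among all that lay inside or within 2000 nt of a span.

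A molecule was an alignment with its 2 letters, and molecules were compared between libraries. Overlap of regions was measured after drawing 6798 unspliced alignments from each library. It is the share of regions with at least 2 alignments in 1 library that were also hit in another. Libraries that share molecules are not independent, and intervals and floors cover counting error only. Alternatives covered the counting of lines, scaling, filters, the second tool, the library label as a block, other region definitions, the leaving out of each library, and several choices made after the data had been seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.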

Results

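Upf1, the RNA helicase at the centre of nonsense-mediated mRNA decay, was immunoprecipitated after ultraviolet crosslinking from mouse embryonic stem cells, and the RNA fragments recovered were sequenced. There were 3 Upf1 libraries from untreated cells and 2 from cells treated with cycloheximide, an inhibitor of translation elongation, and the same numbers of control IgG libraries. The 10 libraries held 833047 lines and 366484 distinct alignments. Among the Upf1 libraries, distinct alignments numbered 97651 in untreated A1, 20449 in untreated A2, 89206 in untreated I, 31792 in cycloheximide A1 and 34220 in cycloheximide A2. Among the IgG libraries they numbered 10299 in untreated A1, 8271 in untreated A2, 47670 in untreated I, 7215 in cycloheximide A1 and 19711 in cycloheximide A2. The libraries were not separate pools of molecules. In IgG untreated A2, IgG cycloheximide A1 and IgG cycloheximide A2, 82.2%, 81.6% and 85.4% of molecules were also present in another library.

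The first comparison asked which RNA was recovered with Upf1 rather than with control IgG. The contig chrRibo held 1.00% ± 0.302 (SD, n = 5) of alignments in the Upf1 libraries and 3.12% ± 1.57 (SD, n = 5) in the IgG libraries. Each Upf1 library (0.707 to 1.46%) lay below each IgG library (1.87 to 5.72%). No single region passed the test between the antibodies. The most heavily covered regions were recovered by both antibodies in all 10 libraries. On chrRibo, positions 6299 to 9294 on the plus strand held 463 of every 100000 unspliced alignments over the Upf1 libraries and 1408 over the IgG libraries. The log2 ratio of Upf1 to IgG there after TMM scaling was -0.65 ± 0.67 (SE). On chromosome 19, positions 5796009 to 5801994 on the minus strand held 536 and 790, while the log2 ratio of Upf1 to IgG after TMM scaling was 0.49.

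The difference in the chrRibo share was -2.11 percentage points, with an exact two-sided permutation p = 0.00794, the smallest this design can give, and an adjusted p of 0.0556 over 7 shares, which did not pass. Among libraries with 38 nt reads it was -2.12 points (exact permutation p = 0.0857, 3 against 4 libraries), and among those with 34 nt reads -1.98 points (2 against 1). It was -12.7 points with every line counted and -5.07 points with distinct molecules. Without the 20 regions with the most alignments it was -0.338 points (exact permutation p = 0.0238), and the antibodies overlapped. Those 20 included large chrRibo regions, so fewer points followed from that setting itself. Alignments on chrRibo fell from 1121 to 278 in Upf1 untreated A1 and from 1386 to 213 in IgG untreated I. The spliced share was 2.52% ± 1.99 in Upf1 and 2.81% ± 2.16 in IgG (SD, n = 5 each, exact permutation p = 0.722). The 3′ side share was 51.2% ± 12.4 in Upf1 and 45.4% ± 7.69 in IgG (SD, n = 5 each, exact permutation p = 0.413).

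Across the 2357 regions, limma-voom called 0 higher and 0 lower in Upf1. At an unadjusted p under 0.05 there were 42 higher and 24 lower, and the trended limma test also called 0. The median log2 ratio of all regions was 0.09 with TMM and -0.90 with library totals. With library totals 0 were higher and 495 lower at an unadjusted p under 0.05, and 3 were called lower. With library totals and without molecules found in more than 1 library, 9 of 1772 were called lower, 866 were lower at an unadjusted p under 0.05 and the median was -1.67. Without IgG untreated A1, 2 were called higher. The regions with the lowest p did not pass, each with an adjusted p of 1.00 by limma. A region on chromosome 4, positions 82975201 to 82975277 on the plus strand, held 38 alignments in 5 of 5 Upf1 libraries (14.2 of every 100000) and 3 in 2 of 5 IgG libraries (3.29 of every 100000), with a log2 ratio of 2.54 ± 0.74 (SE). Another on chromosome 4, positions 119198095 to 119198145 on the minus strand, held 36 and 4, with a log2 ratio of 2.47. These were the 2 called without IgG untreated A1. Regions on chromosome X (40607296 to 40607350, plus strand), chromosome 16 (78777938 to 78777985, minus strand) and chromosome 9 (52913475 to 52913512, minus strand) had log2 ratios of 2.15, 1.96 and 1.91. In the other direction, chrRibo positions 5075 to 5139 on the plus strand held 12.7 of every 100000 alignments in Upf1 and 95.5 in IgG, with a log2 ratio of -2.43. Regions on chromosome 2 (27395331 to 27395444, minus strand), chromosome 11 (83310880 to 83310918, plus strand), chromosome 9 (7793583 to 7793693, plus strand) and chromosome 18 (35100518 to 35100563, minus strand) had log2 ratios of -2.07, -1.92, -1.83 and -1.53. They held only 10 to 15 alignments each over all libraries, and 10 of the 13 on chromosome 11 came from IgG untreated A1. The regions called with library totals were that on chrRibo and those on chromosomes 2 and 11. Among untreated libraries alone, a comparison added after the data had been seen, 0 were called, but 8 were lower with library totals, 38 without Upf1 untreated A2, and 2628 of 203521 with no filter.

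The second comparison asked how blocking translation changed the RNA recovered. In the Upf1 libraries, spliced alignments made up 4.68% ± 0.528 (SD, n = 2) with cycloheximide and 1.08% ± 0.153 (SD, n = 3) without. The control IgG libraries moved alike, with 5.08% ± 0.994 (SD, n = 2) and 1.29% ± 0.488 (SD, n = 3). Alignments on the 3′ side of spliced spans made up 38.7% ± 1.53 (SD, n = 2) in the Upf1 libraries with cycloheximide and 59.5% ± 6.76 (SD, n = 3) without. In IgG these shares were 40.2% ± 2.57 (SD, n = 2) and 48.9% ± 8.30 (SD, n = 3). Alignments shorter than 30 nt made up 51.3% ± 1.35 (SD, n = 2) in Upf1 with cycloheximide and 19.6% ± 10.3 (SD, n = 3) without, and 50.5% ± 2.97 (SD, n = 2) and 20.4% ± 16.3 (SD, n = 3) in IgG.

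Within Upf1 alone, 2 libraries against 3 cannot give an exact permutation p under 0.1, which all 3 of these shares reached. Over all 10 libraries, with labels permuted within each antibody, the spliced share rose by 3.69 percentage points (exact permutation p = 0.01, the smallest possible, adjusted p = 0.035). The 3′ side share fell by 14.8 points (exact permutation p = 0.01, adjusted p = 0.035). The share of short alignments rose by 30.9 points (exact permutation p = 0.02, adjusted p = 0.0467). This test, the spliced and 3′ side shares and the limit of a short alignment were chosen after the data had been seen. The adjustment does not cover that choice. The test also treated the libraries as independent, but IgG cycloheximide A1 and A2 shared 81.6% and 85.4% of their molecules with other libraries. Upf1 cycloheximide A1 and A2 shared 30.6% and 36.1% with other libraries. Between these 2 Upf1 libraries, 18.4% of the smaller one's positions were shared. The p-values of this test, and the SDs of the cycloheximide groups, may thus be too small. The tests within Upf1 alone and of single regions share this limit. Each of the 4 cycloheximide libraries lay above each of the 6 untreated libraries in the spliced share. In the 3′ side share the highest cycloheximide library, at 42.0%, lay just below the lowest untreated library, IgG untreated A1, at 42.2%. With every line counted IgG untreated A1 lay at 36.3%, below all 4 cycloheximide libraries (exact permutation p = 0.05). With distinct molecules it lay at 38.2% and the highest cycloheximide library at 39.9% (exact permutation p = 0.04), and within 1000 nt of a span they lay at 33.1% and 36.0% (exact permutation p = 0.06). The spans came from the spliced alignments of all libraries, and so depended in part on the cycloheximide libraries. With the spans of Upf1 untreated A1 and I alone the 3′ side share fell by 12.0 points (exact permutation p = 0.01). Among libraries with 38 nt reads the differences were 3.63, -11.2 and 22.9 points, each with the smallest exact permutation p possible there, 0.0556. The p for the 3′ side share was 0.075 without IgG cycloheximide A1 and also without IgG cycloheximide A2 (exact permutation), and whether its change differed between the antibodies was not tested.

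**Figure D1:**
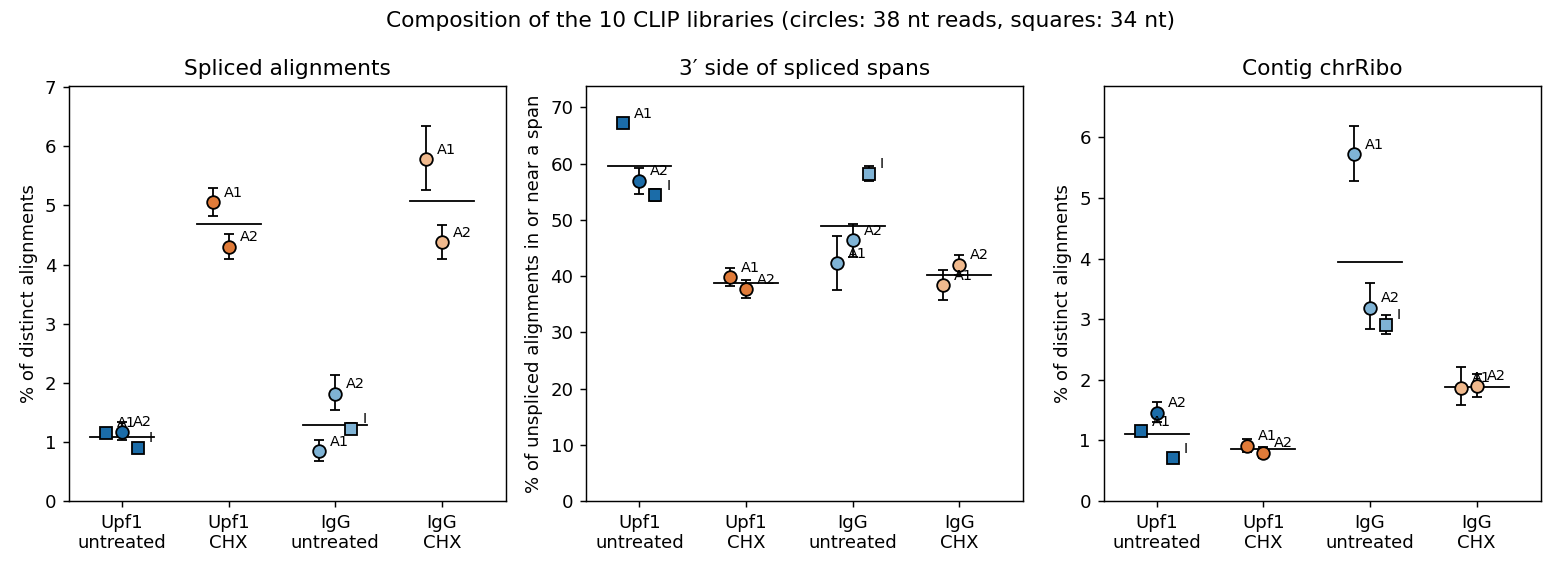
Spliced alignments, alignments on the 3′ side of spliced spans and alignments on the contig chrRibo, in percent, for each of the 10 CLIP libraries by antibody and treatment (CHX, cycloheximide). Points are libraries with Wilson 95% intervals, lines are group means, and the spliced share lies between 4.30 and 5.78% in the cycloheximide libraries and between 0.845 and 1.81% in the untreated ones.

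Single regions also differed with cycloheximide in the Upf1 libraries. Of 2357 regions, 56 were higher and 8 were lower. On chromosome 17, 3 of the 10 named higher regions lay within 1415 nt on the minus strand. Of these, positions 45707647 to 45707707 held 19 alignments with cycloheximide and 0 without, at least 20.6-fold higher. Positions 45707145 to 45707517 held 56 and 10, 18.3-fold higher.

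By limma-voom the log2 changes at these positions were 5.24 ± 1.16 (SE, adjusted p = 0.0158) and 4.71 ± 1.23 (SE, adjusted p = 0.0236). At the third, 45708489 to 45708559, there were 21 alignments with cycloheximide and 1 without, a ratio of 68.5 with a 95% counting interval of 11.0 to 2831. A further region on chromosome 17, positions 35972659 to 35972941 on the minus strand, held 19 and 2, a ratio of 31.0 with an interval of 7.47 to 274. On chromosome 1, positions 155325176 to 155325314 and 164640773 to 164640832, both on the minus strand, were at least 17.4-fold and at least 10.9-fold higher. On chromosome 3, positions 145311557 to 145311712 on the minus strand and 102853549 to 102853625 on the plus strand were at least 15.2-fold and at least 13.0-fold higher. Positions 35065634 to 35065740 on the minus strand of chromosome 18 were at least 12.0-fold higher, and positions 132424054 to 132424108 on the plus strand of chromosome X at least 10.9-fold.

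Among the lower regions, positions 21718652 to 21719612 on the plus strand of chromosome 10 held 81 alignments without cycloheximide and 0 with it, at least 8.28-fold lower (log2 change -4.35 ± 1.03, SE, adjusted p = 0.0164, limma). Positions 133635303 to 133636258 on the minus strand of chromosome 7 held 70 and 0, at least 7.16-fold lower. On chromosome 4, minus strand, positions 41061488 to 41062420 were at least 5.01-fold lower, and positions 131887844 to 131888763 held 67 and 1, a ratio of 20.6 with an interval of 3.57 to 824. Positions 120668396 to 120669116 on the minus strand of chromosome 11 were at least 5.11-fold lower, and positions 74575958 to 74576689 on the plus strand of chromosome 1 at least 3.99-fold. On chromosome 2, positions 172181635 to 172182204 on the minus strand and 31536184 to 31536671 on the plus strand were each at least 3.58-fold lower.

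The higher regions were short, with a median width of 84.5 nt, against 826 nt for the lower ones and 234 nt for regions not called. Their median numbers of alignments were 12, 58.5 and 15. Regions were built by merging pooled alignments, so width may follow the number of alignments. The contrast in width may thus reflect which regions could be called, and this was not tested. Of the 56 higher regions, 43 held no alignment in untreated Upf1 libraries, and 54 had the same sign of change in IgG, as had 1655 of the 2293 regions not called. In IgG, 31 of these 54 and 106 of these 1655 had an unadjusted p under 0.05 by limma-voom. The median log2 change of the higher regions was 2.20 in IgG and 3.92 in Upf1. Higher and lower regions were called by their change in Upf1, so the Upf1 medians and rates in this paragraph tend to be inflated. Set beside those of IgG, they cannot show a larger change in Upf1. The 43 could be tested only if an IgG library held them too, since a region had to be present in at least 3 libraries. Of the 8 lower regions, 7 had the same sign in IgG, but 0 of these at an unadjusted p under 0.05, and the median log2 change was -0.97 in IgG and -3.56 in Upf1. Together the higher regions held 951 and 818 of every 100000 alignments in Upf1 cycloheximide A1 and A2, and 1559 and 1013 in IgG cycloheximide A1 and A2. In the untreated libraries they held 4.95 to 15.5 of every 100000 in Upf1 and 48.8 to 369 in IgG. Since the IgG cycloheximide libraries shared 81.6% and 85.4% of their molecules with others, the rates were also taken over alignments with a molecule found in 1 library alone, and were 1506 and 1146 there and 49.5 to 239 in the untreated IgG libraries. The rates of 1506 and 1146 rested on 19 and 32 alignments. They cannot exclude carry-over, since a carried molecule could lack a visible source. In IgG alone, limma-voom called 0 regions higher and 1 lower, chrRibo positions 11735 to 12022 on the plus strand, with a log2 change of -4.48 ± 1.05 (SE, adjusted p = 0.0467). At an unadjusted p under 0.05 IgG had 117 higher and 39 lower, and the trended limma test called 0. Without molecules found in more than 1 library this balance was 24 and 71 of 1772, and 178 and 3 with library totals besides. The median log2 change of all regions in IgG was -0.22, but 0.20 without IgG cycloheximide A1 and -0.48 without IgG cycloheximide A2. No region was called lower in IgG without Upf1 untreated A2, Upf1 cycloheximide A1, Upf1 cycloheximide A2, IgG untreated I or IgG cycloheximide A1. The test of the difference between the antibodies called 0 regions, with 33 higher and 35 lower at an unadjusted p under 0.05, and 0 by the trended limma test. Among the 415 regions with at least 30 alignments it called 3 higher and 0 lower, and IgG alone had 7 higher and 1 lower. These 3, singled out after their values had been seen, lay on chromosome 10 (82417872 to 82418158, minus strand), chromosome 6 (3151517 to 3151671, plus strand) and chromosome X (73374359 to 73374458, minus strand), each with an adjusted p of 0.0359 by limma. On chromosome 10, the region held 74.7 of every 100000 alignments with cycloheximide and 15.1 without in Upf1, and 11.7 and 128 in IgG.

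The counts of 56 and 8 depended on single libraries, on scaling, on how lines were counted and on the filter. They were 0 and 0 with every line counted, 0 and 0 of 203521 regions with no filter, 0 and 0 without Upf1 cycloheximide A1, and also without Upf1 cycloheximide A2. They were 4 and 0 without Upf1 untreated A1, 1 and 0 without Upf1 untreated I, 85 and 4 without Upf1 untreated A2, 113 and 74 without IgG untreated A1, and 90 and 54 without IgG untreated I. They were 0 and 0 of 480 regions among libraries with 38 nt reads, which include a single untreated Upf1 library. Without molecules found in more than 1 library they were 10 and 3 of 1772 regions, of which 9 and 2 were among the 56 and 8. The median log2 change of all regions was -0.65 with TMM and -0.91 with library totals, which gave 51 and 43. Over both antibodies together, from the treatment term of the model with antibody and added after the data had been seen, cycloheximide gave 134 higher and 25 lower of 2357. These counts were 60 and 4 without Upf1 cycloheximide A1 and 45 and 3 without Upf1 cycloheximide A2, but 148 and 175 without IgG untreated A1. They were 13 and 6 of 1772 without molecules found in more than 1 library, 1 and 1 with every line counted and 0 and 0 of 480 with 38 nt reads.

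**Figure D2:**
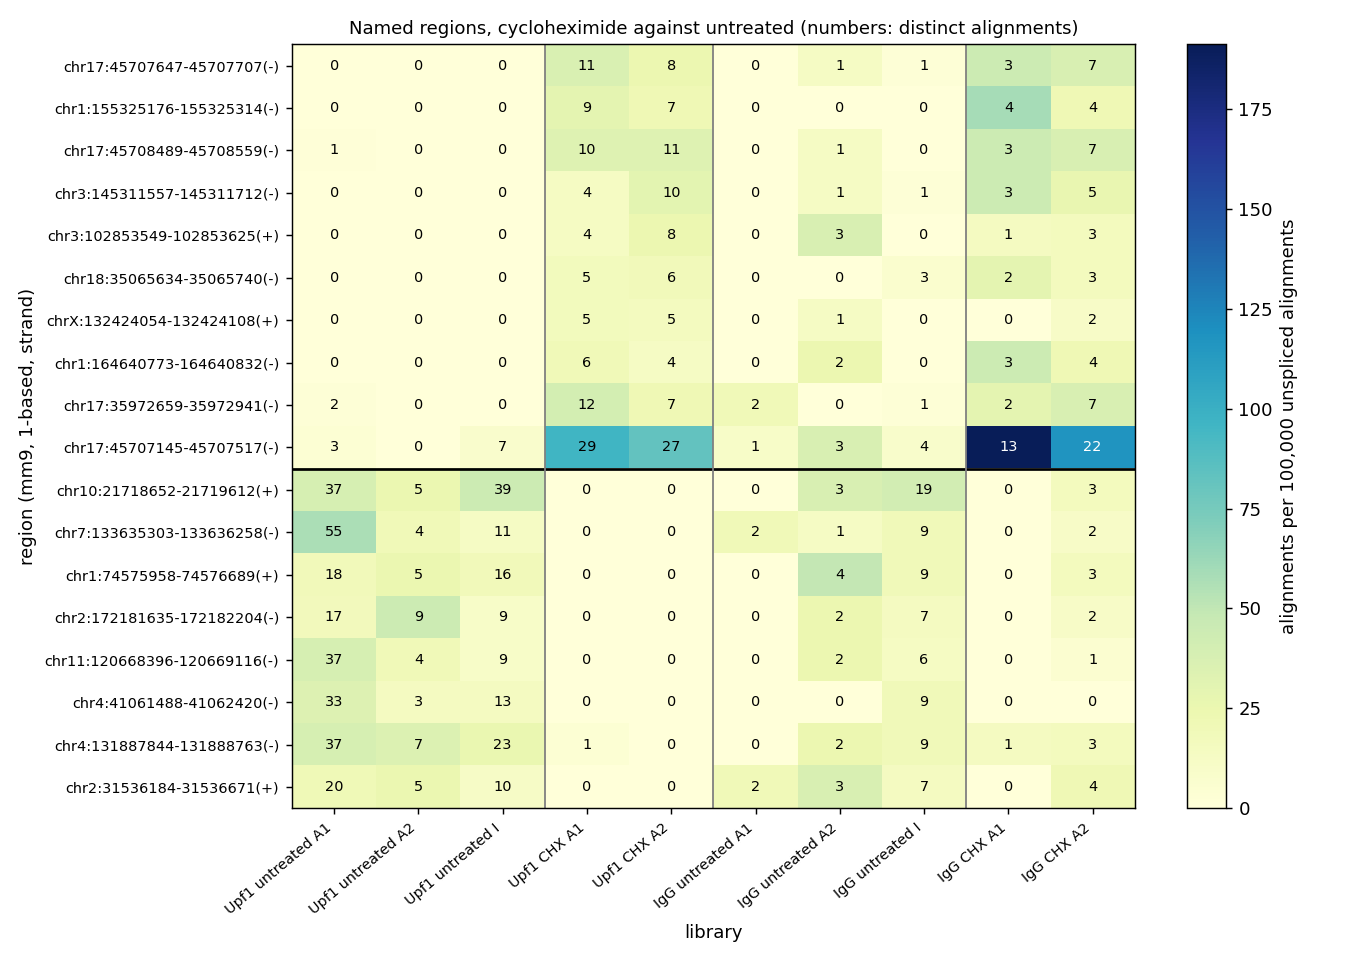
Distinct alignments in the 18 regions named for cycloheximide against untreated in Upf1 (vertical axis, mm9 positions) in each of the 10 CLIP libraries (horizontal axis). Numbers are alignments and color is alignments per 100000 unspliced alignments, with the 10 higher regions above the line and the 8 lower regions below it.

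The third comparison asked how far libraries of 1 antibody shared their regions. At equal depth, 26.1% of a library's regions were also hit in another library of the same antibody, and 29.6% in a library of the other antibody. The difference was -3.53 percentage points (exact permutation p = 0.183 over 126 splits of the 10 libraries). Without the molecules found in both libraries of each pair it was -2.17 points (exact permutation p = 0.111), and with all alignments -8.06 points (exact permutation p = 0.0714). Leaving out each library gave -6.18 to -1.98 points. Grouped by treatment instead, a comparison added after the data had been seen, the shares were 33.9% within and 22.9% between, a difference of 11.0 points (exact permutation p = 0.0143 over 210 splits). Without the molecules found in both libraries of each pair it was 8.13 points (exact permutation p = 0.00952). All libraries with 34 nt reads were untreated, so treatment and read length partly coincided. Grouped by read length the difference was 6.28 points (exact permutation p = 0.208), 13.7 points with all alignments (exact permutation p = 0.0333) and -1.42 points without the molecules found in both libraries (exact permutation p = 0.692). Counting regions with at least 1 alignment, it was 5.81 points by read length (exact permutation p = 0.025) and 3.33 points by treatment (exact permutation p = 0.0524). Among the libraries with 38 nt reads alone, the difference by treatment was 13.7 points (exact permutation p = 0.0286 over 35 splits). The difference by treatment did not pass without Upf1 cycloheximide A1 (9.43 points, exact permutation p = 0.0714) or without IgG cycloheximide A1 (7.83 points, exact permutation p = 0.0833).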

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

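All tests of explanations in this part were chosen after the results they bear on had been seen. Looking for a library far from the rest in 16 sets of 5 libraries found 5, where chance gives about 1 in 20. The mitochondrial share was 0.604% in Upf1 untreated I and 0.587% in IgG untreated I, each far above the other 4 libraries of its antibody. In Upf1 untreated A1, 62.4% of distinct alignments had more than 1 line, with 1.80 lines per distinct alignment. In IgG untreated A1 there were 22.1 lines per distinct alignment.

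Molecules with the same ends, strand and 2 random letters appeared in more than 1 library more often than after shuffling the letters. In the untreated Upf1 libraries the share was 0.796% in A1 (0.488% shuffled), 28.8% in A2 (8.33%) and 3.77% in I (0.696%). In the Upf1 cycloheximide libraries it was 30.6% in A1 (6.75%) and 36.1% in A2 (8.44%). In the untreated IgG libraries it was 3.43% in A1 (2.84%), 82.2% in A2 (22.8%) and 7.20% in I (1.61%). In the IgG cycloheximide libraries it was 81.6% in A1 (19.2%) and 85.4% in A2 (18.2%).

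Of 45 pairs of libraries, 12 shared more than 5% of the smaller library's positions, a limit set after the pairs had been seen. These 12 were all pairs among the cycloheximide libraries, all pairs among the A2 libraries, and the pair of the untreated I libraries. Sharing thus coincided in part with treatment and with the label A2. Letters were compared only at shared positions that held 1 molecule in each library. In the 12 pairs they were equal at 83.6% or more of these positions, and at no more than 14.1% after any shuffle. At these positions, fragments that share both ends by chance are argued against. A whole library deposited under more than 1 label is argued against too, since no pair shared more than 27.4% of the larger library's positions. Up to 65.3% of the smaller library's positions were shared, so this does not bear on part of a library placed under another label. Carry-over of molecules between libraries sequenced together may have produced the sharing and stays open. All 12 pairs joined libraries of the same read length. But positions and molecules were matched on both ends, so a fragment longer than the shorter reads could not match between read lengths. The pattern by read length thus follows in part from the matching, and cannot tell whether carry-over occurred. Molecules with 2 to 20 copies were shared more often than those with 1 copy in 19 of 24 directions. Sharing did not rise steadily with copies, though, since molecules with 2 to 20 copies were not shared more often in the other 5 directions and those with more than 20 copies were shared less often than those with 1 in 11 of 24, and no biological explanation was tested.

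The spliced share was higher with cycloheximide in both antibodies. Longer reads in these libraries are argued against, since among libraries with 38 nt reads the lowest cycloheximide bound was 4.09% and the highest untreated bound 2.12%. A few loci are argued against as well, since without the 20 loci holding the most spliced alignments these bounds were 3.82% and 1.97%. Carry-over from Upf1 libraries may have made the rise in IgG and stays open, since 59.2% or more of molecules in the Upf1 cycloheximide libraries were read once, so a carried molecule could lack a visible source. Among IgG alignments with at least 1 molecule found nowhere else by 5′ end, the bounds were 3.76% and 2.84%, and by both ends 3.88% and 2.63%. Where no molecule of an alignment was shared they were 4.17% and 3.93% by both ends but overlapped by 5′ end, at 4.06% and 4.86%, with 16 spliced of 529 alignments left in IgG untreated A2, and an effect of cycloheximide on the RNA also stays open.

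No region was called between Upf1 and IgG. Other splits of the libraries cannot test a count of 0, which 100 of 100 splits must reach, so they say nothing about chance. The highest of the other splits called 176 regions. It set 3 Upf1 untreated libraries, IgG untreated A2 and IgG untreated I against the rest, which were IgG untreated A1 and the cycloheximide libraries. Treatment was also a term of that model. The split thus compared IgG untreated A1 with the other untreated libraries, and the cause of its calls was not tested.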

How the results depend on the processing

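The settings limited to 38 nt reads, shared molecules, distinct molecules, 1 kb around spans, both antibodies together, untreated libraries alone, library totals without shared molecules, and overlap by treatment or read length were chosen after the data had been seen, and the causes of the changes were not tested. Within antibody, the 3′ side change with cycloheximide was -13.4 with every line counted (exact permutation p = 0.05), -10.5 within 1 kb (0.06) and -11.2 with 38 nt reads (0.0556), and -16.5 to -12.5 leaving out each library. With 38 nt reads the spliced change was 3.63 and the short alignment change 22.9 within antibody, and in Upf1 alone short alignments changed by 19.9, chrRibo by -0.602 and plus strand by 0.738. Leaving out each library, the spliced change in Upf1 was 3.23 to 3.97 and the chrRibo change within antibody ranged from -1.41 to -0.706. The chrRibo difference between antibodies was -2.11 with the label as a block (exact permutation p = 0.0625, the smallest possible over 32 sign choices) and -2.12 with 38 nt reads, while -12.7 with every line, -5.07 with distinct molecules and -0.338 without the 20 regions with the most alignments kept p under 0.05. Of 13 correlations between libraries of the same label, 7 exceeded 0.1 (-0.17 to 0.42), and those of 24 pairs of different label ran from -0.51 to 0.28. These values are not independent, since deviations within a group of 2 libraries mirror each other, and they leave a partial pairing open. The main tests did not treat the labels as pairs, although the rule for named regions, set earlier, did.

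Differences between Upf1 and IgG that had not passed also moved. The mitochondrial difference was -0.108 with 38 nt reads (exact permutation p = 0.0286), and the plus strand difference -1.95 without shared molecules (0.0317) and -1.27 with 38 nt reads (0.0286). The spliced difference turned to 0.0429 with every line and 0.307 with 38 nt reads. The short alignment difference turned to 3.26 with every line, 0.602 with distinct molecules and 7.14 with 38 nt reads. With cycloheximide within antibody, the mitochondrial change turned to 0.0142 with 38 nt reads, and the plus strand change to 1.17 without shared molecules and 0.255 with 38 nt reads. Leaving out each library gave -0.181 to 0.00233 for mitochondrial, 9.64 to 21.8 for more than 1 line, -1.1 to -0.545 for plus strand, -0.923 to 0.453 for spliced and -5.79 to 4.86 for short alignments between antibodies.

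Regions higher and lower with cycloheximide in Upf1 numbered 0 and 0 with every line counted, 133 and 17 with median-of-ratios scaling, 51 and 43 with library totals, 0 and 0 with no filter, 13 and 1 of 415 with at least 30 alignments, 93 and 3 with the trended test, 105 and 15 with the label as a block, 117 and 69 of 3949 in 1 kb windows, 30 and 13 of 1698 with overlapping alignments only, 10 and 3 of 1772 without shared molecules, 9 and 3 of 1772 with library totals besides and 0 and 0 of 480 with 38 nt reads. Leaving out each library gave 0 to 113 higher and 0 to 74 lower. For both antibodies together they were 1 and 1 with every line, 0 and 0 with no filter, 12 and 1 with at least 30 alignments, 220 and 82 in 1 kb windows, 13 and 6 without shared molecules, 23 and 0 with library totals besides and 0 and 0 with 38 nt reads, with 8 lower by the trended test and 9 with the label as a block. Leaving out each library gave 45 to 151 higher and 3 to 175 lower. Between antibodies, library totals gave 3 lower, and 9 lower with shared molecules left out besides, and leaving out each library gave 0 to 2 higher. Among untreated libraries alone 1 was lower with every line, 8 with library totals, 7 without shared molecules besides and 2 with at least 30 alignments, namely chrRibo 5075 to 5139 and chromosome 6 3151517 to 3151671, and with no filter 1 was higher and 2628 lower. Leaving out each library gave 0 to 8 higher and 0 to 38 lower. The change with cycloheximide differed between antibodies in 3 regions, all higher, with at least 30 alignments. Overlap by treatment was 3.33 points with at least 1 alignment (exact permutation p = 0.0524) and 7.83 to 14.3 leaving out each library. By read length it was 5.81 with at least 1 alignment, 13.7 with all alignments, -1.42 without shared molecules and 4.29 to 11.1 leaving out each library. In these results 206 other values under other settings, and 288 that leave out a library, were taken as unchanged. Of these, shares and overlaps kept their direction and side of the threshold or moved by less than the spread. Counts of regions equalled the main count or lay near it, which includes counts of 0 that stayed 0. Under other settings 51 values moved further, 9 turned, 8 no longer passed and 5 newly passed. Leaving out each library, these numbers were 31, 12, 4 and 5. With library totals and no shared molecules the log2 ratios of the 5 regions named as higher in Upf1 turned to -0.15 and -0.49 on chromosome 4 (82975201 and 119198095), -0.71 on chromosome 9, -0.19 on chromosome X and -0.65 on chromosome 16. No other named region turned, while 77 values under other settings and 74 that leave out a library no longer passed. Tests of genes, transcript parts and gene lists were not run. Depth limited what could be called in simulated data with a dispersion of 0.3: of 50 regions changed 8-fold, 3 were recovered at the depth of these libraries and 28 at 20 times that depth for cycloheximide in Upf1, and 31 and 49 for Upf1 against IgG.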

Other observations

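The 5 regions with the most alignments were shared by all 10 libraries. Besides the 2 described above, chrRibo positions 9814 to 11468 on the plus strand held 266 of every 100000 unspliced alignments over the Upf1 libraries and 996 over the IgG libraries. The log2 ratio of Upf1 to IgG there after TMM scaling was -0.86 ± 0.70 (SE). Positions 95823439 to 95824888 on the minus strand of chromosome 11 held 141 and 177, and positions 92481418 to 92484075 on the minus strand of chromosome 5 held 97.4 and 103, while their log2 ratios of Upf1 to IgG after TMM scaling were 0.83 and 1.05. None of the 5 passed the test between antibodies or between treatments in Upf1.

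Set against the spans of spliced alignments from all libraries, 6 of the 56 regions higher with cycloheximide lay inside a span (10.7%), against 53 of 2254 regions not called (2.35%, Fisher's exact test p = 0.00258). This comparison was chosen after the data had been seen, and the cycloheximide libraries supplied many of the spans. With the spans of Upf1 untreated A1 and I alone the excess was not seen, with 0 of 56 and 21 of 2254 inside a span, and these were too few to test it.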
